A study of Mus musculus with 24 samples.

How the data were processed

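The measurements were dual-colour hybridisations of liver RNA on oligonucleotide arrays printed in house, per the labels, with the RNA of mice injected with tumor cells and of mice injected with PBS in the 2 channels. There were 12 biological pairs, 4 at each of 18, 72 and 192 h, each on dye-swapped arrays, 24 arrays in all. Groups, replicate numbers and the dye of each RNA were taken from the labels. Dye-swapped arrays of a pair share their RNA and were counted as 1 replicate.

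Each array came as 3 tables of spots, which hold the same spot positions at rising brightness and were treated as repeat scans. Per the file headers, each table gives the spot intensity of channels A and B already corrected for background, together with the background, flags and a saturation factor, which is a fraction between 0 and 1. The image analysis software and its settings are not given in the sources used here. Spots flagged X hold 0 for intensity and background in the deposited tables and were treated as not measured. The log2 ratios in the deposited table of the series hold the authors' own processed values for the same arrays. Set against the scans, they correlated with the log ratios computed here at 0.52 to 0.87 per array, their medians lay between -0.0334 and 0.00949, and dye-swapped arrays had already been turned the same way. Their exact scale, centring and direction are unstated and were inferred from this comparison.

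Which dye channel A holds is not stated in the files. It was taken to be Cy3, the usual order, and if that is wrong every sign turns. The deposited log ratios cannot settle it, as their own direction is unstated. The scans carry spot positions but no probe numbers, so the numbered probes of the value table were tied to positions by block order, which the correlations above bear out. Gene symbols came from the platform's annotation table, with symbols updated by Entrez identifier through a RefSeq gene list of assembly GRCm38.p6. Of 10080 spots, 9066 had 1 gene symbol, 12 had several and 1002 had none listed, and 8977 Entrez identifiers were matched. No genome build is named for the probes, so no coordinates are given. Control spots cannot be told from other unnamed spots and stayed in the normalization. Unnamed probes and those with several symbols were tested (171 and 6 of those kept) but not named. Where several probes named a gene (21 genes), the brightest stood for it in gene lists.

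Each scan was normalized within the array by loess (span 0.3) on the deposited background-corrected intensities, as log2 of the channels' ratio. Spots with an intensity of 0 or less in either channel were left out. Ratios were turned to tumor over PBS, averaged over the scans in which the spot was not saturated (over all scans where every scan was saturated), and averaged over the dye-swapped arrays. Up to 30.0% of the measured spots of an array were saturated in the brightest scan and up to 8.15% in the dimmest. In the middle scan the median total over background intensity of an array was 1.65 to 2.50 in Cy3 and 1.43 to 2.74 in Cy5, so that a large part of the signal of a typical spot was background. A probe was kept where its total intensity was above 1.5 times the background in either channel, in any scan, on at least 12 arrays, and where both orientations of at least 3 of 4 pairs were measured at each time point. All 10080 probes met the first rule, and 2062 met the second.

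The plan fixed before the data were examined was to correct the background by normexp with an offset of 50. This was changed. On simulated scans normexp stretched the ratios, with a slope of 2.12 against the simulated ratios where plain subtraction had 1.00 (2.08 against 0.963 with the dimmest 20% of spots blanked). The change was made after the normexp results had been seen (0 probes in all comparisons, and 0, 1 and 8 gene lists at 18, 72 and 192 h) and before any call with the subtracted intensities was computed. The simulation built each spot as background plus signal, with a floor under its mean signal. The slope of 1.00 for subtraction therefore follows from the construction. The simulation shows that normexp takes away too much there. It cannot show that subtraction is right for real spots, or how normexp treats spots dimmer than that floor. Normexp is kept as an alternative for every result.

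Ratios were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3, version 1.17.8 of data.table), with a coefficient for each time point over all 12 pairs, which share a single estimate of the spread. Contrasts between the times and the mean of the times came from the same fit. P-values are two-sided and adjusted by Benjamini-Hochberg over the 2062 probes within a comparison, with a threshold of 0.05. A standard error (SE) is that of limma's fit. The probe tests were also run on simulated data for the 2062 probes with 200 changed. They recovered 49.3%, 50.7% and 41.8% of the probes changed by a log2 of 0.5 at 18, 72 and 192 h, and 95.5%, 91.0% and 94.0% of those changed by a log2 of 1. Those shares hold for a spread like the simulated one and for 200 probes changed at once. With fewer changed probes the adjustment is stricter, so the shares do not tell how often a lone change of that size would be called.

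Before the data were examined 37 gene lists were fixed, of pathways, protein complexes and markers of the cell types a liver sample can hold, and the 22 with at least 5 measured genes were tested. Untested lists included interferon response (2 measured genes), cytokine and STAT3 response (4), negative acute phase proteins (4) and cell cycle (4). Neutrophil (3) and lymphocyte (2) markers were also untested, so nothing is concluded on any of these lists. The test was limma's camera on moderated statistics, rewritten for missing values and equal to limma's own on complete simulated data, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 22 lists. Because the preset correlation lies far below most of the correlations estimated here, it makes p-values small. Each call is therefore given with the p from an estimated correlation as well, and 0 lists passed with it at any time point. The limma function fry, run with missing pair values filled by the mean of the time point, also called 0 lists. It tests a list against no change and not against the other genes, so its p answers another question. That p is among the alternatives whose ranges are given below.

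The rule for named genes was fixed with the lists. At each time point the named genes were to be the 10 passing probes of highest and the 10 of lowest ratio with the same sign in all 4 pairs. Where fewer than 10 passed, the 10 named probes of smallest p in each direction were taken and given as not passing. The 3 members of each called list with the largest change in the direction of the call were added. For time contrasts and the mean of the times the rule named passing probes alone, and there were 0.

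Alternatives covered the background (none, normexp), the normalization (print-tip loess, median centring, scaling between arrays), the filter, each scan alone, saturated readings, all 24 arrays with a dye term and the pair as a random block, each time point alone, array weights (statmod 1.5.0), a replicate block, a batch term for replicates 1 and 2 against 3 and 4 (an order seen in the running numbers of the titles), channels as unpaired samples, the deposited value table, other list tests, and leaving out each pair. Scan dates and slides were not used here, as the tables give none. The highest correlation between any arrays was 0.624, so none was counted as deposited more than once, and the lowest between arrays of the same dye orientation was -0.11.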

Results

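Liver gene expression was compared between male C57Bl/6 mice given a subcutaneous injection of 1e+06 LL/2(LLC1) cells in 300 µl of phosphate-buffered saline (PBS) and mice given PBS alone. LL/2(LLC1) is a Lewis lung carcinoma line that forms tumors in mice of this strain. The mice were 8 weeks old, and livers were taken 18, 72 and 192 h after the injection. RNA of a tumor liver and a PBS liver was hybridised together on an oligonucleotide array, and each such biological pair was hybridised again with the dyes exchanged. The design held 4 biological pairs at each of 3 time points, on 24 arrays, each scanned 3 times at rising brightness. The labels call the pairs biological replicates without saying whether a sample is a single animal.

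The arrays differed widely in how many spots were measured. A single array gave between 1136 and 9477 spots. Spots measured in both dye orientations numbered 4580, 1208, 7742 and 7849 in pairs 1 to 4 at 18 h. At 72 h they numbered 8077, 6438, 1087 and 7609, and at 192 h 1627, 4092, 5319 and 3622. A set of 2062 probes for 1861 genes was measured in at least 3 pairs at each time point and was tested. Over these probes the log2 ratios of dye-swapped arrays, turned to the same direction, correlated at 0.16, -0.20, 0.04 and -0.18 in pairs 1 to 4 at 18 h. At 72 h the values were -0.09, 0.01, -0.001 and -0.02, and at 192 h 0.58, -0.20, -0.29 and 0.22. These are correlations across genes, which are not independent replicates. With signs as scanned, the median correlation was 0.21 between arrays of opposite dye orientation and 0.27 between those of the same orientation. The dye thus weighed heavily in the ratios of single arrays. After the mean dye effect was removed the correlations of dye-swapped arrays ran from 0.08 to 0.74. The number of arrays limits the precision of every ratio, and the median standard error of a probe's log2 ratio was 0.15 at 18 and 192 h and 0.16 at 72 h.

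**Figure D1:**
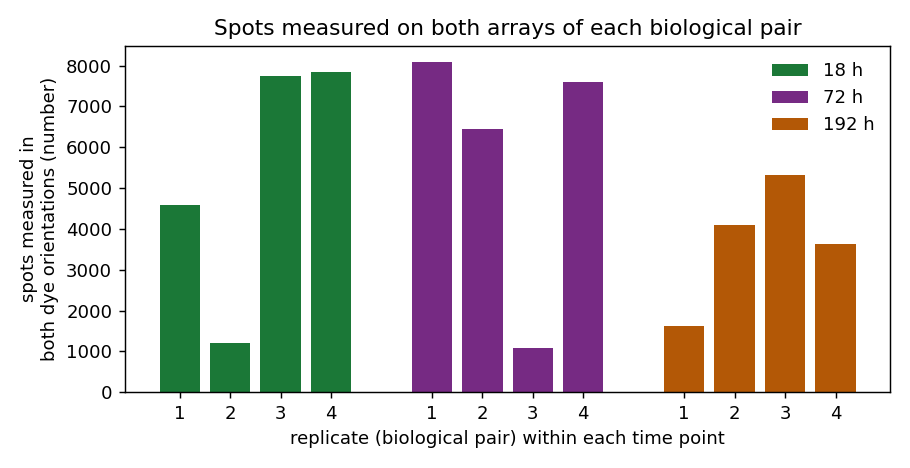
Bars give the number of spots measured on both dye-swapped arrays of each biological pair (y axis, number of spots) against the replicate number within each time point (x axis), coloured by time after injection. Pair 2 at 18 h (1208 spots), pair 3 at 72 h (1087 spots) and pair 1 at 192 h (1627 spots) were the sparsest.

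The comparison at 18 h asked which liver transcripts differed between tumor and PBS mice soon after the injection. Genes of amino acid catabolism and the urea cycle, which break down amino acids and dispose of their nitrogen in hepatocytes, fell as a group (limma's camera test, two-sided, adjusted p = 0.00664 with a preset correlation between genes). That call was lost with an estimated correlation between genes (adjusted p = 0.706 with an estimated correlation, range over 26 alternatives 4.93e-05 to 0.706). This test sets a list against the other tested genes, so that a list rises or falls relative to them. Log2 ratios are tumor over PBS, a direction that rests on reading channel A of the scans as Cy3, which the files do not state. If that reading is wrong, every sign turns. Of the 24 members 18 were lower, with a median log2 ratio of -0.22, most of it from pair 1. The medians over the members were -0.62, 0.02, -0.12 and -0.08 in pairs 1 to 4. Its lowest member was Mat1a, which makes S-adenosylmethionine, at -0.67 ± 0.35 (SE, n = 4 pairs, lower in all 4). It was followed by Cth, which makes cysteine from cystathionine, at -0.66 ± 0.24 (n = 3), and Tdo2, the first enzyme of tryptophan breakdown, at -0.61 ± 0.26 (n = 4).

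Cytosolic ribosomal protein genes rose as a group at 18 h, with 28 of 32 higher and a median log2 ratio of 0.11 (adjusted p = 0.00855; adjusted p = 0.706 with an estimated correlation), but their shift turned downward under median centring without loess (adjusted p = 0.625). Genes of mitochondrial oxidative phosphorylation also rose, with 32 of 47 higher and a median of 0.07 (adjusted p = 0.0303; adjusted p = 0.706 with an estimated correlation), and these too turned downward under median centring (adjusted p = 0.735). Over 26 alternatives the adjusted p ran from 3.00e-09 to 0.957 for the ribosomal list and from 2.30e-05 to 0.966 for the oxidative phosphorylation list. The leading ribosomal members were Rpl29 at 0.31 ± 0.16 (SE, n = 3), Rps15 at 0.28 ± 0.21 (n = 4, negative under median centring) and Rpl13a at 0.23 ± 0.22 (n = 4, negative under median centring). For oxidative phosphorylation the leading members were the ATP synthase subunits Atp5e at 0.75 ± 0.23 (n = 3) and Atp5j2 at 0.36 ± 0.21 (n = 3, negative under median centring) and the complex I subunit Ndufv2 at 0.33 ± 0.16 (n = 3). Kupffer cell and macrophage markers had positive ratios for 6 of 7 genes (adjusted p = 0.237). Hepatocyte markers had them for 7 of 12 (adjusted p = 0.600) and endothelial markers for 2 of 5 (adjusted p = 0.697), and none of these lists passed. Neutrophil and lymphocyte markers had too few measured genes to be tested.

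No single transcript passed at 18 h. With limma 0 of 2062 probes were called, with 124 at an unadjusted p under 0.05 (45 higher, 79 lower) where 103.1 are expected with no effect. Over 34 alternatives, some with other numbers of probes, the count at that p ran from 2 to 218. The smallest adjusted p was 0.290, for Nfkbil1, a relative of the IκB inhibitors of NF-κB, at a log2 ratio of 1.35 ± 0.26 (SE, higher in 3 of 3 pairs). Other positive ratios of small p were those of Gpr65, a proton-sensing receptor of immune cells (0.81 ± 0.20), the Myb-binding nucleolar protein Mybbp1a (0.68 ± 0.18) and the cytochrome c oxidase assembly factor Coa3 (0.45 ± 0.13, higher in 3 of 4 pairs). They were followed by Cuta (0.59 ± 0.20), Tspan2 (0.49 ± 0.18), Mvb12a (0.49 ± 0.16), Marveld3 (0.68 ± 0.25, higher in 2 of 3 pairs) and Atp5e. Itih3, a plasma inter-alpha-trypsin inhibitor heavy chain among the acute phase proteins, had 0.56 ± 0.16 and was positive in 4 of 4 pairs. Negative ratios of small p included those of the paraoxonase Pon3 (-0.65 ± 0.16), the fatty acid elongase Elovl2 (-0.90 ± 0.23), the lysosomal lipase Lipa (-0.73 ± 0.22) and Ugdh, which makes UDP-glucuronate (-0.82 ± 0.23). The autophagy proteins Map1lc3b (-0.61 ± 0.17) and Gabarapl2 (-0.60 ± 0.18, positive in 1 of 3 pairs) and the endoplasmic reticulum (ER) stress protein Herpud1 (-0.72 ± 0.18) were also among them. The acetyl-CoA transporter Slc33a1 (-0.72 ± 0.20), Nipa2 (-0.54 ± 0.16) and Sub1 (-0.48 ± 0.15) were the others. Adjusted over the list alone, 1 acute phase gene (Itih3, adjusted p = 0.0433), 1 fatty acid and triglyceride synthesis gene (Elovl2, adjusted p = 0.0228) and 1 ER stress gene (Herpud1, adjusted p = 0.0249) passed, against 0 over all probes. Here and below that adjustment was made within each of the 22 lists and not across them, so some passes are expected with no effect.

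The list calls at 18 h hung on single pairs and on the background correction. With normexp, the correction first planned, 0 lists were called, with adjusted p = 0.0672 for amino acid genes and 0.145 each for the ribosomal and oxidative phosphorylation lists. Without pair 3 only 1 list was called, as the ribosomal and the oxidative phosphorylation lists had adjusted p = 0.548 each, and without pair 2 there were 5. The oxidative phosphorylation list also missed the threshold without pair 4 (adjusted p = 0.0835), and the amino acid list without pair 1 (adjusted p = 0.0535). The running numbers of the titles split the replicates into 1 and 2 against 3 and 4, a grouping tested alone only after results were seen. Replicates 1 and 2 alone gave 0 lists, and the ribosomal (adjusted p = 0.957) and oxidative phosphorylation (adjusted p = 0.966) lists turned downward in them. Replicates 3 and 4 alone gave 4, with 3 of them shared with all pairs.

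At 72 h cytosolic ribosomal protein genes again rose as a group, with 28 of 32 higher and a median log2 ratio of 0.14 (limma's camera test, adjusted p = 2.99e-06; adjusted p = 0.989 with an estimated correlation, range over 26 alternatives 3.19e-08 to 0.989). This list was called whichever pair was left out (highest adjusted p = 0.00188) and under median centring (adjusted p = 0.000120). Its medians were 0.23, 0.15, 0.27 and -0.18 in pairs 1 to 4, so that pair 4 went the other way. The estimated correlation between its members was 0.688, so that its 32 genes varied largely together from pair to pair. Its leading members were Rps10 at 0.45 ± 0.16 (SE, higher in 4 of 4 pairs), Rpl29 at 0.27 ± 0.16 (n = 3) and Rpl13a at 0.26 ± 0.22 (4 of 4). Oxidative phosphorylation genes were higher relative to the other genes, with 28 of 47 above 0 and a median of 0.04 against -0.05 over all probes (adjusted p = 0.0263; adjusted p = 0.989 with an estimated correlation, range over 26 alternatives 0.00351 to 0.989). Their leading members were the cytochrome c oxidase subunit Cox7c (0.30 ± 0.15, 4 of 4 pairs), Atp5e (0.25 ± 0.20, n = 4, negative under median centring and under print-tip loess) and Atp5k (0.23 ± 0.21, n = 4). Kupffer cell and macrophage markers were split into 4 higher and 3 lower (adjusted p = 0.0957). Hepatocyte markers were split 6 to 6 (adjusted p = 0.478) and endothelial markers 3 to 2 (adjusted p = 0.232).

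Single transcripts did not pass at 72 h either. With limma 0 of 2062 probes were called, with 117 at an unadjusted p under 0.05, 27 higher and 90 lower, and the smallest adjusted p was 0.733. The median log2 ratio over all 2062 probes was itself -0.05, which tilts that split toward lower. The count of 117 ran from 2 to 305 over 34 alternatives. The negative ratios of smallest p included those of Pklr, the liver pyruvate kinase of glycolysis (-0.79 ± 0.18, SE, lower in 3 of 3 pairs), Hadhb, the beta subunit of the mitochondrial trifunctional protein of fatty acid oxidation (-1.004 ± 0.26, 3 of 3), and Apoa5, an apolipoprotein that controls plasma triglycerides (-0.53 ± 0.15, 4 of 4). The others were Narf (-0.58 ± 0.13), the ER thioredoxin-like protein Txndc12 (-0.53 ± 0.14) and Tprgl (-0.78 ± 0.21). Below these came Zbtb4 (-0.73 ± 0.21), the RNA helicase Ddx3x (-0.50 ± 0.15), 1700069L16Rik (-0.47 ± 0.15) and Abhd14a (-0.39 ± 0.12). Positive ratios of smallest p were those of Cdan1, mutated in congenital dyserythropoietic anaemia (0.52 ± 0.13, 3 of 3), the TAK1-binding protein Tab3 (0.46 ± 0.14) and Asb12 (0.44 ± 0.15). Next came Ttll11 (0.55 ± 0.19), the splicing regulator Rbm10 (0.39 ± 0.13), Rps10, C330018D20Rik (0.30 ± 0.11) and Rex1bd (0.44 ± 0.16). Syvn1, a ubiquitin ligase of ER-associated degradation (0.88 ± 0.33), and the intestinal alkaline phosphatase Alpi (1.73 ± 0.66, negative under print-tip loess) were positive in 2 of 3 pairs each. Adjusted over the list alone, 1 gene of fatty acid and triglyceride synthesis (Pklr, adjusted p = 0.00970) and 1 of fatty acid oxidation (Hadhb, adjusted p = 0.0261) passed, and 0 did over all probes.

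The oxidative phosphorylation call at 72 h was lost without pair 3, the sparsest (adjusted p = 0.183), under median centring (adjusted p = 0.425) and with the normexp correction first planned (adjusted p = 0.137). It was also lost once each pair's trend with spot intensity was removed (adjusted p = 0.115). The list's statistic then went only from 3.041 to 2.225, so this loss decides nothing about such a trend. Without pair 4 the number of called lists went from 2 to 6. Replicates 1 and 2 alone gave 8 lists, 1 of them shared with all pairs, and replicates 3 and 4 alone gave 2, with 0 shared.

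At 192 h the number of shifted gene lists was 9, with ER stress, acute phase and ribosomal protein genes higher and several metabolic lists lower. With an estimated correlation 0 of the 9 were called (adjusted p = 0.483 to 0.690), and with fry, which tests against no change and not against other genes, 0 were. Genes of ER stress and the unfolded protein response rose, with 10 of 12 higher. Their median log2 ratio was 0.16 (limma's camera test, adjusted p = 0.00129; adjusted p = 0.483 with an estimated correlation, range over 26 alternatives 7.12e-05 to 0.483). Its leading members were the ER chaperones and cofactors Pdia4 (0.51 ± 0.22, SE, higher in 3 of 3 pairs), Hyou1 (0.36 ± 0.27, 2 of 3) and Dnajc3 (0.35 ± 0.15, 3 of 3). Positive acute phase protein genes, whose products the liver secretes in inflammation, rose with 8 of 11 higher. Their median was 0.12 (adjusted p = 0.00614; adjusted p = 0.521 with an estimated correlation, range 2.84e-06 to 0.841). Itih3 led them at 0.70 ± 0.16 (4 of 4 pairs), and was the 1 member that passed adjusted over the list alone (adjusted p = 0.00721), against 0 over all probes. Lrg1, a leucine-rich plasma glycoprotein, followed with 0.44 ± 0.25 (2 of 4, with 1 pair at 1.70), and the fibrinogen chain Fga with 0.40 ± 0.19 (3 of 4, with 1 pair at -0.59). Cytosolic ribosomal protein genes rose with 23 of 32 higher and a median of 0.09 (adjusted p = 0.00391, and adjusted p = 0.690 with an estimated correlation). The adjusted p of this list ranged from 3.32e-08 to 0.892 over the alternatives, the upper end being that of fry. Its leading members were Rpl35 (0.25 ± 0.17), Rps10 (0.21 ± 0.16) and Rps15 (0.20 ± 0.21, 2 of 4 pairs, negative in the deposited log ratios). The ER stress list was called whichever pair was left out (highest adjusted p = 0.0436), though not under median centring (adjusted p = 0.0815). The acute phase list was lost without pair 2 (adjusted p = 0.0579), pair 3 (adjusted p = 0.0568) or pair 4 (adjusted p = 0.611) and under median centring (adjusted p = 0.141), and it turned downward with replicates 1 and 2 alone (adjusted p = 0.841). The ribosomal list was lost without pair 3 (adjusted p = 0.468), turned downward without pair 1 (adjusted p = 0.0528), and was lost under median centring (adjusted p = 0.833).

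Metabolic lists fell at 192 h, in amino acid, bile acid, fatty acid, drug and energy metabolism. Among genes of bile acid synthesis and transport 9 of 10 were lower, with a median log2 ratio of -0.28 (adjusted p = 0.00391; adjusted p = 0.483 with an estimated correlation, range over 26 alternatives 0.000102 to 0.711). The leading members were the hydroxysteroid dehydrogenase Akr1c6 (-0.65 ± 0.27, SE, lower in 3 of 4 pairs), the sterol transporter Abcg8 (-0.41 ± 0.14, 3 of 3, positive under median centring) and the oxysterol hydroxylase Cyp7b1 (-0.40 ± 0.34, 2 of 3). Genes of amino acid catabolism and the urea cycle had 20 of 24 lower and a median of -0.22 (adjusted p = 0.00148; adjusted p = 0.521 with an estimated correlation, range 1.13e-06 to 0.602). They were led by the cysteine dioxygenase Cdo1 (-0.56 ± 0.25), Tdo2 (-0.56 ± 0.26, lower in 2 of 4 pairs) and Bhmt, which remethylates homocysteine (-0.47 ± 0.28, 2 of 4). Genes of fatty acid oxidation and ketogenesis had 12 of 14 lower and a median of -0.21 (adjusted p = 0.00218; adjusted p = 0.483 with an estimated correlation, range 0.000771 to 0.483). At their head were the fatty acid hydroxylase Cyp4a10 (-0.64 ± 0.29, lower in 2 of 4 pairs), the short-chain acyl-CoA dehydrogenase Acads (-0.34 ± 0.13) and Hadhb (-0.31 ± 0.26). Genes of fatty acid and triglyceride synthesis had 13 of 16 lower and a median of -0.19 (adjusted p = 0.00979; adjusted p = 0.521 with an estimated correlation, range 6.38e-05 to 0.611). The lowest members were the desaturase Scd1 (-0.55 ± 0.42, lower in 2 of 4 pairs and positive with array weights), the elongase Elovl3 (-0.37 ± 0.29) and Pklr (-0.36 ± 0.16). Cytochrome P450 and drug metabolism genes had 17 of 20 lower and a median of -0.15 (adjusted p = 0.00391; adjusted p = 0.483 with an estimated correlation, range 1.00e-04 to 0.618). The glucuronosyltransferase Ugt2b5 (-0.88 ± 0.30), Cyp2j5 (-0.48 ± 0.21) and Gstz1 (-0.31 ± 0.13) led them. Oxidative phosphorylation genes had 35 of 47 lower and a median of -0.07 (adjusted p = 0.0277; adjusted p = 0.690 with an estimated correlation, range 3.13e-09 to 0.802), and the lowest were Ndufa6 (-0.35 ± 0.17, 2 of 4 pairs), Atp5j (-0.32 ± 0.17) and Ndufb4 (-0.31 ± 0.18). In each of these 6 lists 0 members passed adjusted over the list alone.

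**Figure D2:**
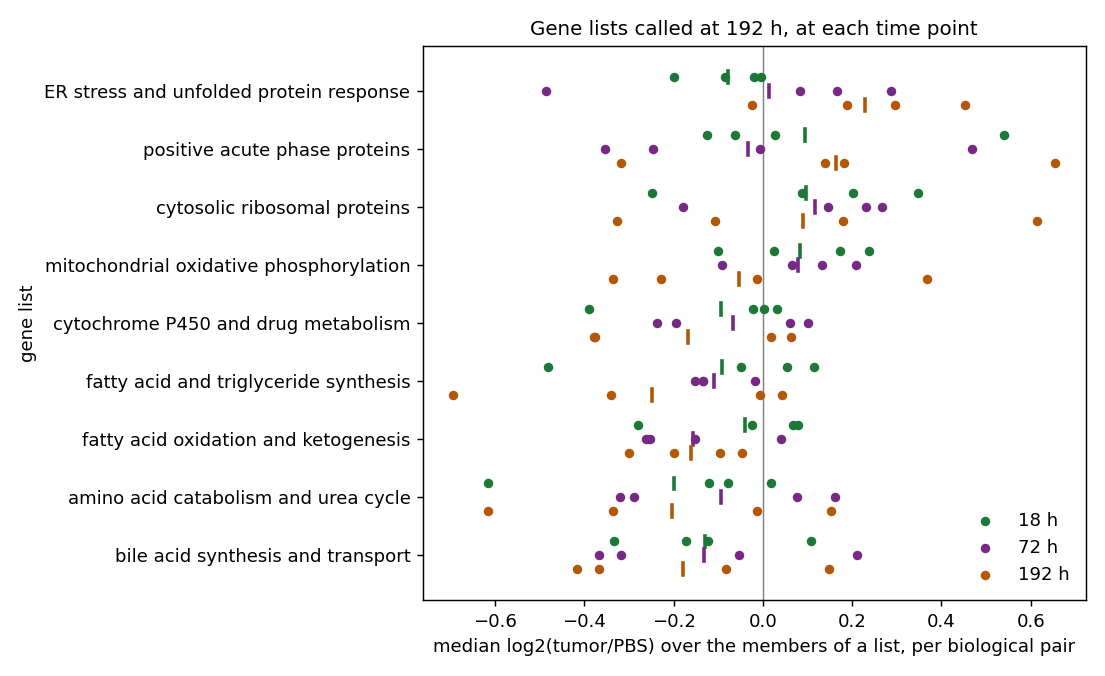
Each point is the median log2(tumor/PBS) over the members of a gene list in a single biological pair (x axis), and short vertical lines are the means of the 4 pairs, for the 9 lists called at 192 h (y axis), coloured by time after injection. At 192 h the pairs of a list lay widely apart and mostly on both sides of 0, and at 18 h the upward shifts of the ribosomal and oxidative phosphorylation lists turned downward under median centring.

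Hepatocyte markers, as the main cell type of the liver, were split 6 to 6 at 192 h (adjusted p = 0.854). Kupffer cell and macrophage markers were split 5 to 2 (adjusted p = 0.465) and endothelial markers 3 to 2 (adjusted p = 0.492). No single transcript passed at 192 h. With limma 0 of 2062 probes were called, and 60 had an unadjusted p under 0.05 (17 higher, 43 lower), fewer than the 103.1 expected with no effect. The median log2 ratio over all 2062 probes was -0.03, which tilts that split toward lower. The count of 60 ran from 0 to 136 over 34 alternatives. The smallest adjusted p was 0.998. After Itih3, the positive ratios of smallest p were those of Sting1, the adaptor of cytosolic DNA sensing (0.71 ± 0.24, SE, higher in 3 of 3 pairs), Klhl22 (0.43 ± 0.15, 4 of 4) and Caml (0.70 ± 0.25). Then came the glucocorticoid modulatory protein Gmeb1 (0.38 ± 0.15), the lipid droplet protein Plin4 (0.46 ± 0.18, 2 of 3) and Kng1, the kininogen precursor of bradykinin (0.42 ± 0.17, 4 of 4). Nin (0.31 ± 0.13, 3 of 4), the interferon-induced ubiquitin-like protein Isg15 (0.38 ± 0.16) and Pdia4 completed them. Negative ratios of smallest p were those of Hes6 (-0.45 ± 0.14), the selenoprotein reductase Msrb1 (-0.35 ± 0.11), Mrpl32 (-0.41 ± 0.14), Nudt4 (-0.52 ± 0.18, lower in 4 of 4 pairs) and the sulfiredoxin Srxn1 (-0.40 ± 0.14, 4 of 4). The others were Ugt2b5 (positive in 1 of 3 pairs), Abcg8 (positive under median centring) and Urah (-0.33 ± 0.12, lower in 4 of 4). The glycolytic enzyme Gapdh (-0.35 ± 0.13, 4 of 4) and the lipid transfer protein Stard10 (-0.36 ± 0.14, 4 of 4) were also among them.

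Pairs 1 and 4 carried most of the metabolic shifts at 192 h apart from oxidative phosphorylation, whose medians were 0.37, -0.23, -0.01 and -0.34 in pairs 1 to 4, so that pair 1 went against its fall. Without pair 4 the number of called lists went from 9 to 2, and without pair 1 to 5, of which 4 were shared. Without pair 4 the adjusted p was 0.476 for bile acid genes, 0.602 for amino acid genes, 0.448 for fatty acid oxidation, 0.611 for fatty acid synthesis and 0.618 for P450 genes. The oxidative phosphorylation list then turned upward (adjusted p = 0.423). Without pair 1 it was 0.120 for bile acid genes, 0.505 for amino acid genes, 0.492 for fatty acid synthesis and 0.175 for P450 genes, and without pair 2 it was 0.801 for oxidative phosphorylation. Under median centring the bile acid list (adjusted p = 0.711) and the fatty acid oxidation, P450 and oxidative phosphorylation lists (adjusted p = 0.0730 each) were no longer called, while the amino acid and fatty acid synthesis lists were (adjusted p = 0.0152 each). With the normexp correction first planned 8 of the 9 lists were called, and oxidative phosphorylation was not (adjusted p = 0.0999). Replicates 1 and 2 alone gave 3 lists (2 shared, with oxidative phosphorylation turned upward at adjusted p = 0.802) and replicates 3 and 4 alone gave 8 (7 shared).

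**Figure D3:**
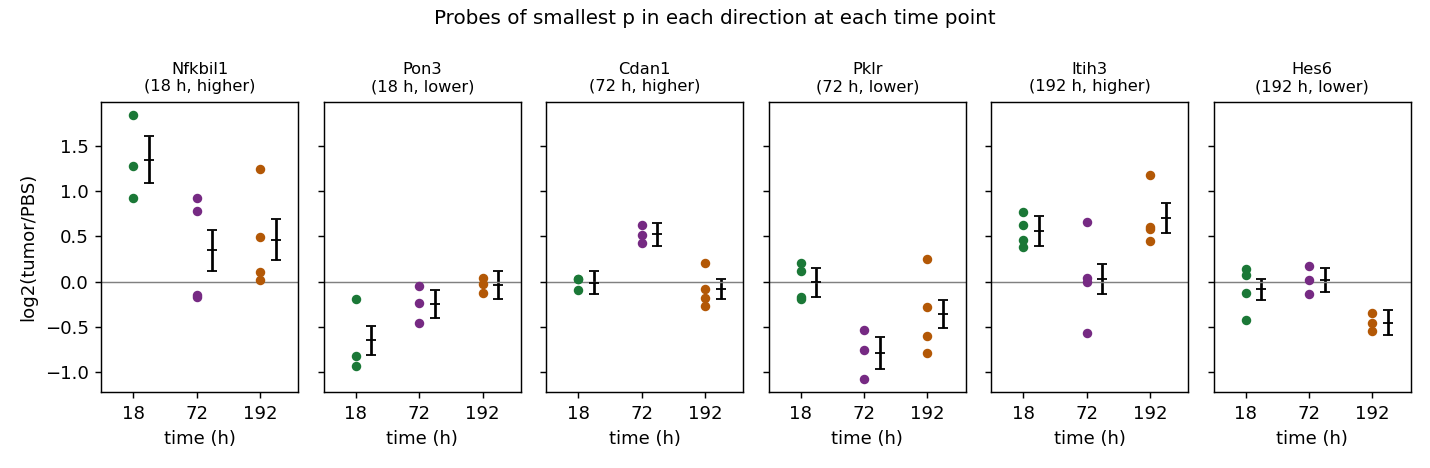
Points are log2(tumor/PBS) of single biological pairs (y axis) against time after injection in hours (x axis), and black bars are limma's mean ± SE at each time, for the probe of smallest p in each direction at each time point. None passed the adjusted test (1.35 for Nfkbil1 at 18 h, -0.79 for Pklr at 72 h), and because each was picked by its p at a single time, its course over time shows no time pattern.

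Whether the difference between tumor and PBS livers depended on time was tested with contrasts between the time points. For no transcript did the test show it. With limma there were 0 of 2062 probes called for 72 h minus 18 h, 0 for 192 h minus 72 h and 0 for 192 h minus 18 h. At an unadjusted p under 0.05 there were 70, 52 and 38 probes, all fewer than the 103.1 expected with no effect, and the smallest adjusted p was 0.900, 1.00 and 0.997. Over 33 alternatives, some with other numbers of probes, these counts ran from 0 to 149, 0 to 138 and 0 to 127, so the shortfall was not stable. Itih3 had a log2 ratio of 0.03 ± 0.16 at 72 h between its 0.56 at 18 h and 0.70 at 192 h, and its difference between 192 h and 72 h was 0.67 ± 0.23 (SE, adjusted p = 1.00). Herpud1 went from -0.72 at 18 h to 0.39 at 72 h, a difference of 1.11 ± 0.26 (adjusted p = 0.995 over all probes), and it was the 1 ER stress gene that passed adjusted over the list alone (adjusted p = 0.0130), a gene singled out after its values were seen. The median standard error was 0.22 for 72 h minus 18 h and for 192 h minus 72 h, and 0.21 for 192 h minus 18 h.

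The effect common to the 3 time points was tested as the mean over all 12 pairs. Again limma called 0 of 2062 probes, with 224 at an unadjusted p under 0.05 (58 higher, 166 lower) against 103.1 expected with no effect, and a median standard error of 0.09. The median log2 ratio over all 2062 probes was -0.03, which tilts that split toward lower. The count of 224 ran from 1 to 418 over 33 alternatives. Nfkbil1 had a mean log2 ratio of 0.72 ± 0.14 (SE, adjusted p = 0.254), the smallest adjusted p of this comparison, and Itih3 had 0.43 ± 0.09 (adjusted p = 0.395). Pklr had -0.39 ± 0.09 (adjusted p = 0.412). These 3 genes were singled out after their values were seen.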

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

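The tests of how many probes other splits call, the reading of the estimated correlation and of the left-out pairs for the lists at 192 h, and the left-out pairs for the time contrasts were chosen only after the result was seen.

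Lrg1 at 192 h drew attention because 1 of its 4 pairs, pair 4, had a log2 ratio of 1.70 while the others lay between -0.07 and 0.15. Fga at 192 h did so because pair 1 had -0.59 while the others lay between 0.64 and 0.89. Of 58 groups of 4 pairs examined, 2 held such a far pair, and chance gives about 1 in 20.

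In 4 cases the shift of a gene list differed between time points by a test of the difference itself. Amino acid catabolism and urea cycle genes were higher at 72 h than at 18 h relative to other genes (adjusted p = 0.0277, median difference 0.08, 16 of 24 members higher; adjusted p = 0.864 with an estimated correlation), and the call was lost without pair 1 (adjusted p = 0.211) or pair 4 (adjusted p = 0.124) at 18 h, or pair 3 (adjusted p = 0.159) or pair 4 (adjusted p = 0.626) at 72 h. Oxidative phosphorylation genes were lower at 192 h than at 72 h (adjusted p = 0.000370, median difference -0.11, 40 of 47 lower; adjusted p = 0.795 with an estimated correlation), which was lost without pair 2 (adjusted p = 0.0558) or pair 4 (adjusted p = 0.778) at 192 h. They were also lower at 192 h than at 18 h (adjusted p = 0.000115, median difference -0.17, 38 of 47 lower; adjusted p = 0.837 with an estimated correlation), which was lost without pair 4 at 192 h (adjusted p = 0.657) and under median centring (adjusted p = 0.308). ER stress genes were higher at 192 h than at 18 h (adjusted p = 0.000115, median difference 0.24, 11 of 12 higher, and adjusted p = 0.837 with an estimated correlation). This call held in all 12 fits that left out a pair (highest adjusted p = 0.0175), with normexp and under median centring. Pairs of 72 h do not enter this difference, so only the fits without an 18 h or a 192 h pair could test it.

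The first pattern weighed is the 9 lists shifted at 192 h. Each scan had already been fitted by loess on intensity, so only a trend with mean spot intensity left in the pairs could be removed here. With it removed, 8 of the 9 lists were still called the same way, which argues against such a leftover trend as their whole source. For oxidative phosphorylation the removal decides nothing, as its statistic went only from -2.54 to -2.15 and its adjusted p from 0.0277 to 0.0771. Under median centring, which takes out no trend with intensity, only the amino acid and fatty acid synthesis lists stayed called (adjusted p = 0.0152 each). The calls therefore hung on how intensity was handled. Members that vary together from pair to pair remain a candidate explanation, as 0 of the 9 lists were called once the correlation was estimated from the pairs (adjusted p = 0.483 to 0.690). So does a single pair, as leaving out pair 4 left 2 lists called (amino acid genes at adjusted p = 0.602). A response of the liver to the growing tumor stays open and is not separated from either of these by 4 pairs.

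The second pattern is the upward shift of ribosomal protein genes at 72 h. After each pair's trend with intensity was removed, the list's statistic went from 5.29 to 3.74 and its adjusted p from 2.99e-06 to 0.00413. That argues against such a trend as the whole source, while a part of the shift may go with intensity. Rank correlations of the ratios with intensity were 0.10, 0.11, 0.30 and -0.02 in pairs 1 to 4. The medians of the list were 0.23, 0.15, 0.27 and -0.18 in the same pairs. Removing each pair's regression on the mean dye effect left an adjusted p of 1.25e-06. Pairs 1 to 4 correlated with that effect at only 0.04, -0.20, -0.07 and -0.07, so its removal could change little and decides nothing. A dye effect that differed between the arrays of a pair was not tested. Shared variation of the members between pairs stays open, as the list lost its call with an estimated correlation (adjusted p = 0.989). Whether the tumor changed the ribosomal transcripts stays undecided with 4 pairs, and the direction of the shift rests on reading channel A as Cy3. The control mice were given PBS without cells, so a tumor effect cannot be told apart from a response to the injected cells.

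Other splits of the pairs were made by turning the signs of pairs. Within a time point there are 8 such splits with the real split among them, too few for a share under 0.05. With limma the real split called 0 probes at 18, 72 and 192 h, as did the others, so that 8 of 8 had as many, which a count of 0 makes certain and which tells nothing. At an unadjusted p under 0.05 the real split had 124 probes at 18 h (highest other 148; as many in 2 of 8 splits), 117 at 72 h (highest other 137; 3 of 8) and 60 at 192 h (highest other 275; 7 of 8). For gene lists the real split gave 3 at 18 h (highest other 6; 5 of 8), 2 at 72 h (highest other 7; 6 of 8) and 9 at 192 h (highest other 8; 1 of 8). The 275 probes of a single other split at 192 h mean that many ratios there were alike in size but opposite in sign between pairs.

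Exchanging pairs between time points gives 35 splits with the real split among them, by the number of probes at an unadjusted p under 0.05 chance was not excluded for any contrast. As many as the real 70 for 72 h minus 18 h were had by 14 of 35 splits (highest other 142), as many as the 52 for 192 h minus 72 h by 29 (highest other 355), and as many as the 38 for 192 h minus 18 h by 33 (highest other 263). For the mean of the times, 8 of 100 splits over the 12 pairs, the real split among them, had as many as the 224 (highest other 346), so chance was not excluded there either. The counts of called probes decide nothing, since every split has at least the real 0: 35 of 35 for each contrast (highest other 0, 1 and 0) and 100 of 100 for the mean (highest other 2).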

How the results depend on the processing

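The normexp correction was fixed before the data and became an alternative after its results were seen. The sparsest pair of each time point left out, replicates 1 and 2 alone, replicates 3 and 4 alone, and a filter of at least 2 pairs were run only after results or files were seen. The count of called probes was 0 in every comparison and alternative except that Nfkbil1 was called at 18 h with the first scan alone (1 probe of 1325, log2 1.31, adjusted p = 0.0466) and Cers2 in the mean of the times with a batch term (1 probe, log2 -0.50, adjusted p = 0.0196), the latter named after its value was seen. Dropping the filter on signal above background removed nothing, so it tests nothing, and fitting each time point alone gives no time contrasts. The number of pairs in which a spot was measured limited which probes could be tested. Named genes kept direction and side of the threshold in 3054 of 3073 values (1 newly called, 18 with the sign turned) and called lists in 266 of 364 (89 lost, 9 turned). The cause was not tested except where fewer pairs were used. No named gene passed in the main fit, so for genes the same side means only that they were still not called. A pair left out at another time point does not enter a ratio, so both shares overstate how stable the results were.

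Lists called at 18, 72 and 192 h numbered 3, 2 and 9. They numbered 0, 1 and 8 with normexp, and 3, 1 and 2 with median centring (at 18 h all 3 lower and only 1 shared, against 2 higher and 1 lower before), which moved the median ratio of all probes to -0.12 at 18 h and -0.27 at 72 h (normexp to -0.14 at 72 h). They numbered 2, 3 and 4 of 17 testable with the deposited value table (2, 1 and 4 shared) and 0 at each time with an estimated correlation and with fry. Leaving out a pair gave 1 to 5 at 18 h, 2 to 6 at 72 h and 2 to 9 at 192 h. Without the sparsest pairs there were 6, 3 and 7 (3, 1 and 4 shared), and with replicates 1 and 2 alone 0, 8 and 3 (0, 1 and 2 shared).

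With the replicate number as a block, 0 probes were called in all comparisons and 3, 2 and 9 lists, all shared, so no call changed. Deviations of same-numbered pairs correlated at -0.23 to 0.46 (mean 0.10), over 0.1 in 6 of 12 cases. Pairs of different number at other time points had a mean of -0.027. Whether the numbers pair some of the samples therefore stays open.

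Signs turned as follows (log2 ratio for a gene, test statistic for a list). With print-tip loess, Alpi had -0.0445 and Atp5e -0.0017 at 72 h. With median centring, Rps15 had -0.14, Rpl13a -0.21, Atp5j2 -0.0186, the ribosomal list -0.748 and the oxidative phosphorylation list -0.523 at 18 h, Atp5e -0.11 at 72 h and Abcg8 0.0140 at 192 h. At 192 h Rps15 had -0.12 with the third scan, -0.0179 with array weights, -0.0242 in the value table, -0.00081 without the sparsest pairs and -0.00081 to 0.4916 over left-out pairs (lowest without pair 1, highest without pair 2), and Scd1 had 0.20 with array weights. Over left-out pairs the ribosomal list at 192 h ran from -2.39 (without pair 1) to 6.074 (without pair 2) and the oxidative phosphorylation list from -6.45 (without pair 1) to 1.58 (without pair 4). Without the sparsest pairs the ribosomal list had -2.46 (adjusted p = 0.0461). With replicates 1 and 2 alone, at 18 h Rpl29 had -0.0095, the ribosomal list -0.108 and the oxidative phosphorylation list -0.0432, and at 192 h Plin4 had -0.0282, the acute phase list -0.201 and the oxidative phosphorylation list 0.445. With replicates 3 and 4 alone, at 72 h Syvn1 had -0.18, Alpi -0.23 and Rpl29 -0.0354.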

Other observations

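The gene lists were also tested on the mean of the times, a test added to the fixed design, whose left-out pairs and scalings were chosen only after the result was seen. Averaged over 18, 72 and 192 h, genes of bile acid synthesis and transport were lower in all 10 measured members (median log2 ratio -0.16, limma's camera test, adjusted p = 0.00418; adjusted p = 0.610 with an estimated correlation). Slc10a1, the sodium-taurocholate cotransporter that takes bile acids up from blood, was the 1 member that passed adjusted over the list alone, at -0.28 ± 0.08 (SE, adjusted p = 0.0327, and 0.412 over all probes). Ribosomal protein genes were higher in 29 of 32 members (median 0.11, adjusted p = 5.04e-07; adjusted p = 0.632 with an estimated correlation). Amino acid catabolism and urea cycle genes were lower in 18 of 24 (median -0.23, adjusted p = 0.00620; adjusted p = 0.632 with an estimated correlation), P450 genes in 16 of 20 (median -0.11, adjusted p = 0.0206; adjusted p = 0.610 with an estimated correlation) and fatty acid oxidation genes in 12 of 14 (median -0.12, adjusted p = 0.0206; adjusted p = 0.610 with an estimated correlation). With normexp only the ribosomal list of these 5 was called (adjusted p = 5.27e-05), and under median centring only the amino acid list (adjusted p = 0.0268). Without pair 4 at 192 h the bile acid (adjusted p = 0.0702), P450 (adjusted p = 0.235), fatty acid oxidation (adjusted p = 0.192) and amino acid (adjusted p = 0.192) lists were lost, and without pair 1 at 72 h the last 3 were (adjusted p = 0.102, 0.102 and 0.0974).

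In the same averages, lipid genes passed adjusted over the list alone in lists that were not called: Lpin2, a phosphatidate phosphatase of triglyceride synthesis (-0.47 ± 0.11, SE, adjusted p = 0.0105), Pklr (-0.39 ± 0.09, adjusted p = 0.0105) and the elongase Elovl2 (-0.40 ± 0.13, adjusted p = 0.0496) in fatty acid and triglyceride synthesis, and Msmo1, a sterol oxidase (-0.43 ± 0.13, adjusted p = 0.0459), in cholesterol synthesis. Itih3 was the 1 such acute phase gene (0.43 ± 0.09, adjusted p = 0.00422). Over all probes each of these had an adjusted p of 0.395 or more, and they were singled out after their values were seen. Kupffer cell and macrophage markers were higher in 6 of 7 members (median 0.07, adjusted p = 0.0596). Growth hormone responsive and male-biased liver genes had a median difference of -0.48 between 192 h and 18 h, with 6 of 7 lower (adjusted p = 0.0872), and did not pass. The medians of this list were 0.07, 0.30, -0.04 and 0.91 in pairs 1 to 4 at 18 h. At 192 h they were 0.40, -0.65, 0.27 and -1.02, so the pairs went both ways. The estimated correlation between its members was 0.686, so that they varied largely together.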
